A study of Mus musculus with 24 samples.

How the data were processed

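Total RNA of 24 placentas was labelled with Cy3 and hybridised to Agilent single-colour arrays, 1 per placenta, per the labels' protocols. Parents were C57Bl6/J and carried 1 null allele of Ndrg1, fetal tissue was typed by PCR for sex and genotype, and membranes were taken off the placentas beforehand, per the labels. Each scanner file holds the spot intensity on a linear scale as Feature Extraction 10.7.3.1 made it per the file headers, with background subtracted and spatial trends removed, and not normalized between arrays. The submitters' processing notes name version 9.1. A value table of the same arrays was deposited by the authors on a log2 scale, with medians between 4.65 and 4.84 per array. It differed from the scanner values by an offset that varied with intensity. The values were not centred per gene, and the method of normalization is not given in the sources used here.

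The arrays lay on 3 slides of 8 arrays, each slide its own scan. Each array had 59305 spots other than controls, for 55681 probes. No spot was saturated, and 4467 spots over all arrays carried an outlier flag (133 to 236 per array) and were left out, which cost 559 probe values. Controls (3671 spots per array) were left out too. The share of spots well above background was 48.1% to 56.9%, with a mean of 52.4%, and the 75th percentile of the signal ran from 211 to 462. The number of arrays limits the precision.

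Spots of a probe were averaged, log2 was taken and the 75th percentile of the array over all probes other than controls was subtracted. A probe was kept if it was well above background on every array of at least 1 group, which left 28790 probes. Probes were named by matching their accession to a RefSeq table (assembly GRCm38.p6), which gave a symbol to 26413 probes and none to 29268. The array design names build mm9, so no coordinates are printed and the table served for names and gene order. The probe with the highest mean stood for a gene, giving 22094 genes, of which 158 had a missing value. Of 4943 genes with several kept probes, probes were called in opposite directions for 1 gene, between the sexes. A gene counted as well above background on an array if any of its probes did, also a probe that was not kept. Its level is that of the chosen probe. A gene not well above background on any array of a group has only a bound there. Its fold is given as "at least", against the mean over the arrays of the higher of the lowest signal well above background and the chosen probe's own signal. Where this holds for some groups of the dimmer side, their arrays alone were raised in this way.

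The 8 groups were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3, data.table version 1.17.8) as a model of group means over all 24 arrays, with 18.1 total degrees of freedom. Contrasts gave hypoxia, knockout and sex averaged over the other factors, hypoxia within each genotype, knockout within each oxygen level, and 3 interactions. All p-values are two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Gene lists (31, with 534 entries, of which 523 were on the array, 495 were measured and 9 were renamed) were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 31 lists of a comparison. The same test with an estimated correlation and fry, which asks whether a list's own genes move one way on balance, were run beside it. Of 310 list tests camera called 86, the estimated correlation 1 (Y-linked genes, between the sexes) and fry 11.

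Named genes followed a rule. For each comparison these were the 10 largest rises and 10 largest falls among called genes with the same sign in every stratum of 3 against 3, or the 5 smallest p where fewer than 5 genes passed. Up to 4 called members per list, Ndrg1 and 11 reference genes were added, and predicted or unnamed transcripts were left out. Lists, comparisons, this rule and the alternatives were fixed before the data were examined, apart from those named as added later. The genes and lists in the plots and Slc45a4 were chosen after their values were seen.

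Slide was tested as a fixed block, as a random block (duplicateCorrelation, correlation 0.274) and by fold changes within slide. The fixed block separates slide from group only through 2 groups that span slides. In male WT hypoxia, array 311 lay on slide 2 and 301 and 302 on slide 1. In female KO normoxia, array 601 lay on slide 2 and 602 and 603 on slide 3. Values under this block thus rest on 311 and 601, and 601 is 1 of the 2 arrays of lowest signal. The block cannot tell slide from what is particular to these arrays. Other alternatives were normexp with offset 50 and quantile normalization, quantile normalization alone, other probe filters, the mean of a gene's probes, eBayes with trend and robust, array weights, the authors' log2 values, fits of only the groups compared, and leaving out each array. The normexp alternative used the median spot signal in place of the mean signal, which the files do not hold, and so counts as added later. Added after the data were seen were fits without the 2 arrays of lowest signal (male WT normoxia 102 and female KO normoxia 601). A further fit also left out male KO normoxia 201, and another left out only the 2 and had a random slide block. No 2 arrays held identical values.

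Shared controls were examined with 100 draws of shuffled residuals, and each count of called genes with 100 splits of the arrays, the real one included. The tests were tested on simulated data of 21936 genes, of which 21736 were left unchanged. For hypoxia averaged over genotype and sex, 55.2%, 89.6% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale were called, and 9 of the unchanged genes. For hypoxia in wild type the shares were 37.3%, 79.1% and 100%, with 14 unchanged genes called. For the knockout in normoxia they were 23.9%, 80.6% and 97.0%, with 6. For the genotype by oxygen interaction they were 14.9%, 62.7% and 86.4%, with 5. The limit first set for recovery at the largest change was relaxed for the interaction after its value was seen. Of 20 simulated lists the 1 shifted by 0.3 was called and no other. The simulated genes varied independently, without a slide effect. The shares and the list result therefore do not show how the tests behave with correlated genes or slides.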

Results

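Gene expression was measured in 24 mouse placentas collected at embryonic day 15.5 (E15.5), with 1 single-colour Agilent array per placenta. The study deleted Ndrg1, a gene induced by low oxygen, and asked how its loss and maternal hypoxia alter the placenta. Placentas fell into 8 groups of 3 by fetal sex, by Ndrg1 genotype (wild type, WT, or knockout, KO) and by the oxygen given to the dam. Hypoxic dams breathed 12% oxygen from E12.5 on. Between 48.1% and 56.9% of the spots of an array were well above background, and 22094 genes entered the tests. The number of arrays limits the precision. The labels do not say which placentas shared a dam, so p-values measure only the spread between these samples. Levels are log2 signals relative to the 75th percentile of the array, and differences are log2 differences ± SE unless stated otherwise.

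Ndrg1, the deleted gene, was lower in every knockout placenta than in every wild type placenta. Its level was 6.41 ± 0.14 (SD, n = 12) in wild type and 2.69 ± 0.85 (SD, n = 12) in knockout placentas. The lowest wild type value was 6.22 and the highest knockout value 3.74, so the genotype labels and the Ndrg1 signal did not contradict each other on any array. The difference was -3.72 ± 0.26, which is 13.2-fold lower in knockouts (adjusted p = 6.86e-07), and it had the same sign in all 4 strata of sex and oxygen. Ndrg1 stayed well above background on all 24 arrays. It was measured by 1 probe whose place relative to the deleted part is not given in the sources used here. Within slide 1 the difference was -3.93 in normoxic males, and within slide 3 it was -3.50 in hypoxic females. Wherever the probe lies, its signal separated the labelled genotypes, but the signal left in knockouts cannot be assigned to a part of the transcript.

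The genes that mark sex followed the labels on 23 arrays and went against them on 1. In the 12 female placentas Xist, the RNA that silences 1 X chromosome, lay between 0.11 and 1.47, and no Y-linked gene was well above background. In 11 male placentas Ddx3y lay between 0.93 and 1.52. The library labelled male KO normoxia 201 had Ddx3y at -5.63, not well above background, and Xist at 1.20. It was kept in its labelled group, and every direction by sex is by label.

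**Figure D1:**
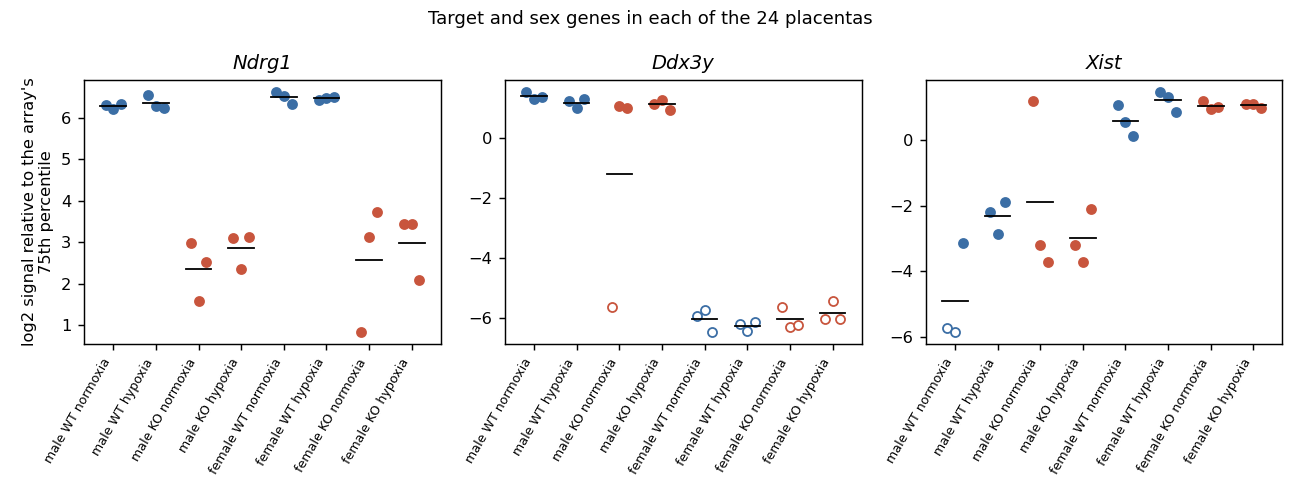
Levels of Ndrg1, Ddx3y and Xist on each array (vertical axes, log2 relative to the 75th percentile of the array) for the 8 groups of 3 placentas (horizontal axis), with wild type in blue, knockout in red, filled points well above background, open points not, and bars at group means. All 12 knockout arrays lie at or below 3.74 for Ndrg1 and all 12 wild type arrays at or above 6.22, and 1 library of the male knockout normoxia group has Ddx3y at -5.63.

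Across both genotypes and sexes, the placentas of hypoxic dams had more Apol11b, a member of the apolipoprotein L family, with a difference of 1.92 ± 0.18 (3.78-fold, 12 against 12 arrays, adjusted p = 4.76e-05). Of the 12 normoxic arrays 10 measured the gene above background. In all, 92 genes rose and 420 fell with hypoxia. The largest rises included Il4i1, an amino acid oxidase of immune cells (1.38 ± 0.27), Fabp6, an intracellular bile acid carrier (1.37 ± 0.30), and Rbp7, a retinol carrier (1.18 ± 0.23), all measured on all 24 arrays. Clec2m (1.68 ± 0.36) and Lilr4b (1.26 ± 0.27) rose as well, with sizes that rest partly on signals not above background. Mpo, the peroxidase of neutrophils, Fcgr2b, an inhibitory antibody receptor, and Ptafr, the receptor of platelet-activating factor, were at least 1.91-fold, 2.02-fold and 2.05-fold higher, since no array of 1 of the 4 normoxic groups measured them. These 5 were above background on 10 to 12 hypoxic arrays and on 4 to 6 normoxic arrays. Among the falls were Sult1a1, a sulfotransferase (-1.03 ± 0.23), Wfdc2, a secreted protease inhibitor (-0.90 ± 0.20), Prss12 (-0.87 ± 0.19) and Angpt1, a ligand of the endothelial receptor Tek (-0.83 ± 0.19, above background on 10 hypoxic and 11 normoxic arrays).

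Lists of oxidative phosphorylation and heat shock proteins were called lower under hypoxia, and those of glycolysis and of targets of hypoxia-inducible factors higher. Of 25 subunits of oxidative phosphorylation 24 were lower and 3 fell past the threshold over all genes, 13 when adjusted over the list alone. The median was -0.14, and Ndufb8 (-0.37 ± 0.06), Uqcrc2 (-0.23 ± 0.05) and Ndufv1 (-0.19 ± 0.05) were the 3 (list adjusted p = 1.05e-06). All 11 heat shock proteins were lower, with a median of -0.17, and Hspe1 (-0.26 ± 0.05) and Hspd1 (-0.24 ± 0.06) fell, 9 when adjusted over the list alone (list adjusted p = 1.33e-05). With an estimated correlation these lists gave adjusted p = 0.333 and adjusted p = 0.207. All 15 glycolytic enzymes were slightly higher, with a median of 0.10 and none past the threshold singly (list adjusted p = 0.00458). Of 30 targets of hypoxia-inducible factors 22 were higher, with a median of 0.14 (list adjusted p = 0.00763). The 3 that rose were Serpine1, an inhibitor of plasminogen activation (0.67 ± 0.16), Hmox1, a haem oxygenase (0.36 ± 0.09), and Car9, a carbonic anhydrase (0.28 ± 0.06), and 4 rose and 2 fell when adjusted over the list alone. Both lists gave adjusted p = 0.470 with an estimated correlation, and neither was called for hypoxia in wild type placentas alone. Ndrg1, left out of the list, had means of 6.29 and 6.36 in normoxic and hypoxic wild type males. In wild type females they were 6.50 and 6.48. The classical targets Vegfa (0.09 ± 0.11, adjusted p = 0.660) and Slc2a1 (-0.07 ± 0.06, adjusted p = 0.489) did not pass.

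Marker lists of several cell types were also called for hypoxia. All 13 macrophage markers were higher, with a median of 0.46; none passed over all genes and 7 rose when adjusted over the list alone (list adjusted p = 1.33e-05). Inflammation genes had a median of 0.53, with 13 of 15 higher (list adjusted p = 0.00456), and with an estimated correlation both lists gave adjusted p between 0.333 and 0.334. Maternal decidua, the uterine tissue attached to the placenta, had a median of 0.75, with 14 of 15 markers higher and Bmp2 past the threshold (0.51 ± 0.11, list adjusted p = 5.10e-05). The mean of this list was -0.31 and 0.090 on the normoxic arrays 102 and 601, those of lowest signal, and 1.26 or higher on the others, and without both the median relative to all genes was 0.34 in place of 0.77. Markers of spongiotrophoblast and glycogen cells had a median of 0.22 (19 of 22 higher, list adjusted p = 9.68e-05) and those of syncytiotrophoblast -0.20 (11 of 14 lower, list adjusted p = 0.0359). These 3 gave adjusted p = 0.470 with an estimated correlation. Angiogenic factors were called higher as a set (median 0.16, 12 of 17 higher, list adjusted p = 0.0258), although the 1 member past the threshold, Angpt1, fell. Interferon response genes were called higher too (median 0.11, 14 of 18 higher, list adjusted p = 0.0352), and these lists gave adjusted p = 0.333 and adjusted p = 0.666 with an estimated correlation.

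The count of genes for hypoxia changed with a block for slide and with the scaling. The fixed block links the slides only through the groups of arrays 311 and 601, the latter of low signal. The 3 slides held 6 and 2, 4 and 4, and 2 and 6 normoxic and hypoxic arrays. With slide as a fixed block 2 genes passed and with slide as a random block 1, Apol11b passing both times. All 512 genes kept their sign, while their median size went from 0.32 to 0.19 (fixed) and 0.29 (random) and their median SE from 0.072 to 0.11 and 0.081. Within slide 1 (male wild type) 509 of them had the same sign and within slide 3 (female knockout) 490, on arrays that are part of the comparison that called them, and 5 of the 11 lists kept call and direction with the block, in which decidua had a median of -0.13 and syncytiotrophoblast turned to 0.00021. Within slides 1 and 3 the medians were 0.75 and 0.06 for macrophages, -0.22 and -0.07 for oxidative phosphorylation, -0.29 and -0.09 for heat shock proteins, 1.84 and -0.28 for decidua, and 0.57 and -0.29 for interferon response. With the percentile taken over probes above background on all arrays 5 genes rose and 1 fell, and with the values normalized by the authors 23 rose and 26 fell. Leaving out 1 array gave between 1 gene (without 402, 502 or 704) and 1162 (without 603), and without the 2 arrays of lowest signal 56.

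**Figure D2:**
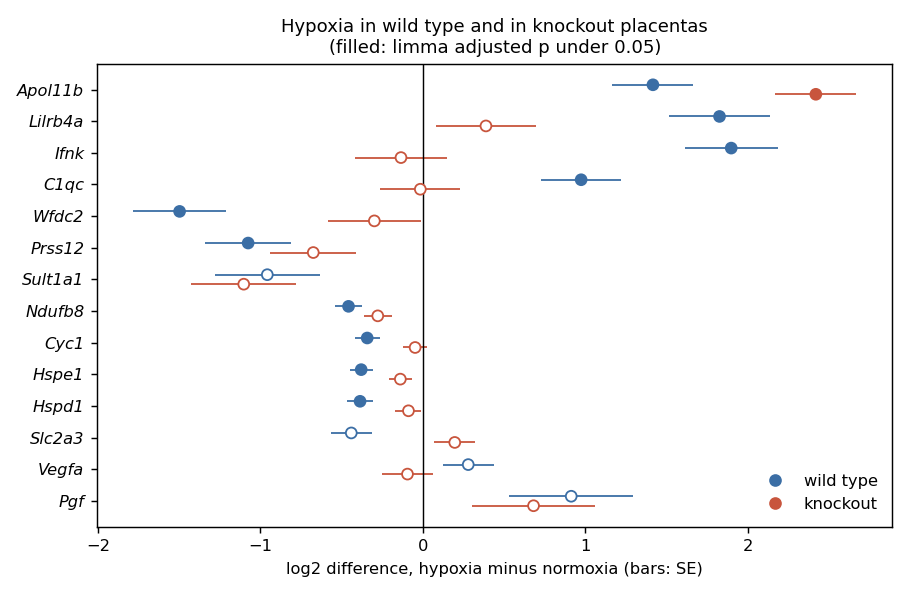
Log2 differences between hypoxic and normoxic placentas (horizontal axis, bars are SE) of 14 named genes, picked after their values were seen, in wild type (blue, 6 against 6 arrays) and knockout placentas (red, 6 against 6 arrays), with filled points at adjusted p under 0.05. Apol11b is at 2.42 in knockouts and Ndufb8 at -0.46 in wild type.

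In wild type placentas alone 192 genes rose and 584 fell with hypoxia. The largest rises included Ltf, the iron-binding protein lactoferrin (at least 3.42-fold, with no array of 1 normoxic group above background, adjusted p = 0.0253), Ifnk, a type I interferon (1.90 ± 0.28, 6 against 6 arrays, adjusted p = 0.0202), and Lilrb4a, an inhibitory receptor of myeloid cells (1.83 ± 0.31, adjusted p = 0.0202). Itgax, an integrin of dendritic cells and macrophages, was 2.38 ± 0.58 higher, with 6 hypoxic and 2 normoxic arrays above background. Its size thus rests partly on signals not above background. Speer2 was not well above background on any normoxic wild type array and was at least 1.79-fold higher in hypoxia, where 3 of 6 arrays measured it (adjusted p = 0.0229). Wfdc2 (-1.50 ± 0.29), Upk3a, a membrane protein of urothelium (-1.20 ± 0.22), and Pla2g10, a secreted phospholipase (-1.08 ± 0.27), were among the largest falls that all 12 arrays measured.

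Of 13 macrophage markers 12 were higher with hypoxia in wild type placentas, with a median of 0.84, and 4 rose over all genes, 10 when adjusted over the list alone. The complement genes C1qa (1.01 ± 0.26), C1qb (0.94 ± 0.26) and C1qc (0.98 ± 0.25) and the macrophage receptor Adgre1 (0.89 ± 0.23) were the 4 (list adjusted p = 2.81e-06). Of 25 subunits of oxidative phosphorylation 9 fell, 18 when adjusted over the list alone, with a median of -0.23 (list adjusted p = 1.34e-09), among them Ndufb8 (-0.46 ± 0.09) and Cyc1 (-0.34 ± 0.08). Both lists gave adjusted p = 0.272 with an estimated correlation, as did the heat shock proteins, of which 4 fell, 8 when adjusted over the list alone (median -0.26, list adjusted p = 7.25e-05). Interferon response genes had a median of 0.30, with 17 of 18 higher and 6 past the threshold when adjusted over the list alone (list adjusted p = 7.25e-05). An estimated correlation ended that call. Tfeb (-0.46 ± 0.09) and Ovol2 (-0.45 ± 0.11), transcription factors of the labyrinth, fell within the syncytiotrophoblast list (median -0.27, list adjusted p = 0.0309), and so did the imprinted gene Slc22a18 (-0.70 ± 0.17) within its own (median -0.32, list adjusted p = 0.0352). Decidua markers had a median of 1.02 (list adjusted p = 0.000268; relative to all genes 1.05, and 0.62 without arrays 102 and 601), inflammation genes 0.50 (list adjusted p = 0.0352), spongiotrophoblast and glycogen cells 0.20 and proliferation genes -0.39 (both list adjusted p = 0.0140). With an estimated correlation these last lists gave adjusted p between 0.564 and 0.671.

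With a fixed block for slide 9 genes passed for hypoxia in wild type, none of them among the 776, and with a random block 0 (limma, 3634 at unadjusted p under 0.05, 5420 without the block). With these blocks 775 and 776 of the genes kept their sign, while their median size went from 0.41 to 0.26 and 0.37 and their median SE from 0.096 to 0.13 and 0.11. Within slide 1, 772 of the 776 had the same sign in males, on arrays that are part of the comparison that called them. Proliferation genes had a median of 0.16 there. Of the 10 called lists 4 kept call and direction with the fixed block, under which the medians turned to -0.40 for decidua, -0.036 for spongiotrophoblast and glycogen cells, 0.012 for syncytiotrophoblast and -0.073 for inflammation, none of them called. Without the 2 arrays of lowest signal 1150 genes passed, and with a random block on top 545, of which 441 were among the 776. Other scalings gave 114 rises and 41 falls (percentile over probes above background on all arrays) and 49 rises and 30 falls (values normalized by the authors), and leaving out single arrays gave between 0 (without 502 or 704, 4610 and 4504 at unadjusted p under 0.05) and 1518 (without 601).

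In knockout placentas Apol11b was the 1 gene called for hypoxia, 2.42 ± 0.25 higher (5.35-fold, 6 against 6 arrays, adjusted p = 0.000283), with 4 of 6 normoxic arrays above background. By limma 1393 genes lay at unadjusted p under 0.05, so the single call does not show that the other genes stayed unchanged. Mycn, a transcription factor of the Myc family, came next at 1.11 ± 0.19 and did not pass (adjusted p = 0.148), nor did Dync1i1 (adjusted p = 0.441), Wscd1 or Zdhhc8. All 23 proliferation genes were higher, with a median of 0.31 (list adjusted p = 3.19e-06), as were all 15 glycolytic enzymes, with a median of 0.14 (list adjusted p = 6.27e-05). Cholesterol synthesis (median 0.16), spongiotrophoblast and glycogen cells (median 0.22; both list adjusted p = 6.27e-05), targets of hypoxia-inducible factors (median 0.17, list adjusted p = 0.00407), decidua (median 0.51, list adjusted p = 0.00553), inflammation (median 0.47, list adjusted p = 0.00729) and angiogenic factors (median 0.23, list adjusted p = 0.0130) were called higher. Genes of p53 and apoptosis (median -0.10, list adjusted p = 0.00571) and heat shock proteins (median -0.09, list adjusted p = 0.00455) were called lower. No member of these lists passed over all genes, 1 of spongiotrophoblast and glycogen cells rose when adjusted over the list alone, and with an estimated correlation they gave adjusted p between 0.385 and 0.611. The 3 measured Y-linked genes were called higher as well (list adjusted p = 0.0391, adjusted p = 0.485 with an estimated correlation), in a comparison that holds the library labelled male KO normoxia 201. With slide as a fixed block 3 genes passed, with a random block 1, Apol11b being among them each time, and 5 of the 11 lists kept call and direction with the block. Within slide 3 decidua and angiogenic factors turned, with medians of -0.28 and -0.19, and without arrays 102 and 601 decidua lay at -0.023 relative to all genes and was not called (adjusted p = 0.693).

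No gene passed the test of whether hypoxia acted differently in the genotypes (limma, 2056 at unadjusted p under 0.05). The smallest p belonged to Ifnk, whose hypoxia difference in knockouts minus that in wild type was -2.03 ± 0.40 (adjusted p = 0.467), followed by Fam205a2, Slamf9, Sez6l and Iigp1, an interferon-induced GTPase (-1.01 ± 0.21), at the same adjusted p. Of the 776 genes called in wild type, 622 had the same sign in knockouts. Over all genes, which are not independent replicates, the hypoxia differences of the genotypes correlated with r = 0.283, and 18 of 100 draws with shuffled residuals gave as high a value. As lists, oxidative phosphorylation (median 0.20), proliferation (0.70; both list adjusted p = 1.99e-08), cholesterol synthesis (0.23, list adjusted p = 0.001), erythroid cells (0.38, list adjusted p = 0.00663), fetal endothelium (0.24, list adjusted p = 0.0160), imprinted genes (0.22, list adjusted p = 0.0270) and heat shock proteins (0.18, list adjusted p = 0.0400) were called with a higher hypoxia difference in knockouts, the last losing its call for 13 of 24 arrays left out singly. Interferon response (median -0.36, all 18 negative, list adjusted p = 3.45e-07) and macrophages (median -0.63, 12 of 13 negative, list adjusted p = 0.000262) were called with a lower one. With an estimated correlation endothelium gave adjusted p = 0.710 and the other 8 lists adjusted p = 0.579, and 3 of the 9 kept call and direction with slide as a fixed block, where 12 genes passed and erythroid cells turned to -0.17 relative to all genes.

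**Figure D3:**
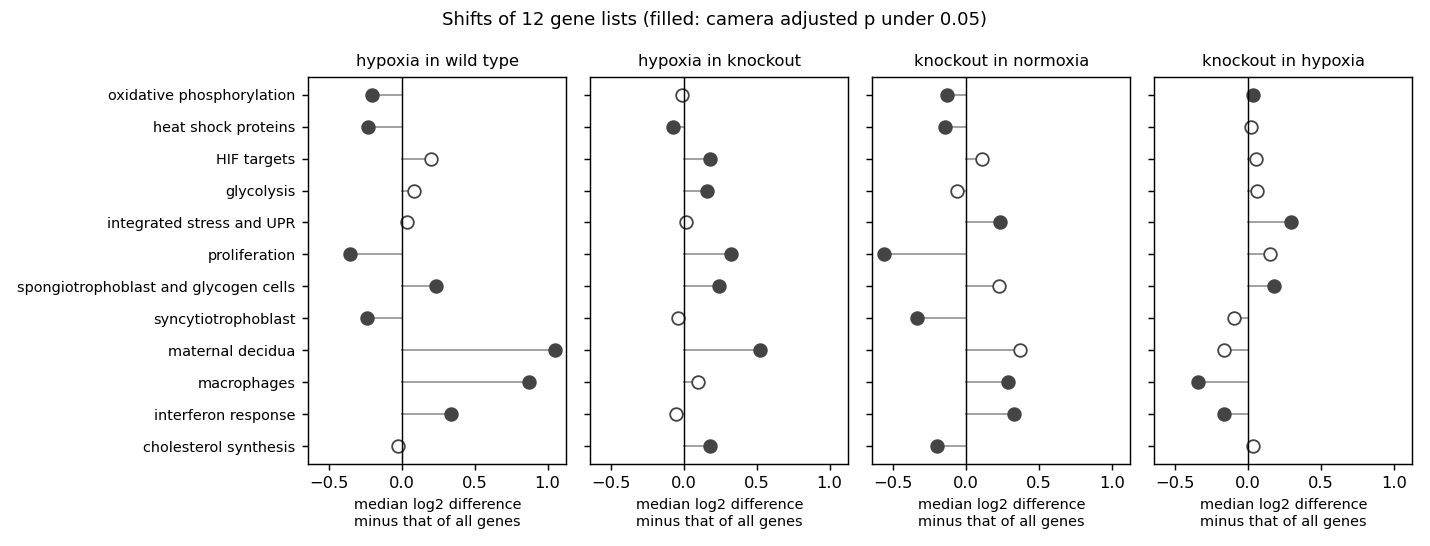
Median log2 difference of the measured members minus that of all genes (horizontal axis) of 12 gene lists, picked after their values were seen, under hypoxia in wild type and in knockout placentas and for the knockout in normoxia and in hypoxia. Filled points have a list adjusted p under 0.05 at the preset correlation. Macrophage markers lie at 0.87 under hypoxia in wild type, the highest of the plotted lists there after maternal decidua.

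Averaged over oxygen and sex, 56 genes differed between knockout and wild type placentas, 10 higher and 46 lower in knockouts, the deleted gene included. The largest rise was that of Gpr20, an orphan G protein-coupled receptor (1.32 ± 0.16, 2.50-fold, 12 against 12 arrays, adjusted p = 0.00107). Fbxo32, a ubiquitin ligase subunit (0.57 ± 0.09), Pcgf2, a Polycomb protein (0.49 ± 0.07), the transcription factor gene Foxd2 (0.69 ± 0.12), Tmem65 (0.50 ± 0.09) and St3gal1, a sialyltransferase (0.34 ± 0.06), rose too. Among the falls were the transporter genes Slc6a13, which carries GABA and taurine (-1.15 ± 0.20), and Slc13a2, which carries dicarboxylates (-0.98 ± 0.17, above background on 10 knockout arrays). S100a14, a calcium-binding protein (-1.30 ± 0.19), the transcription factor gene Six2 (-0.92 ± 0.15), Adcyap1r1, a receptor of the neuropeptide PACAP (-0.86 ± 0.15, above background on 11 knockout arrays), Fndc7 (-0.83 ± 0.12) and Strip2 (-0.70 ± 0.10) fell as well. Scube3 and Dennd3 were at least 2.04-fold and at least 1.30-fold lower (adjusted p = 0.0469 and adjusted p = 0.0208). They were above background on 2 of 12 knockout arrays each, with none in 2 and 3 of the 4 knockout groups, against 9 and 7 wild type arrays.

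Called genes lay close to Ndrg1 on chromosome 15. Among the 50 tested genes on either side of it 6 of 100 were called, Fbxo32, Tmem65, St3gal1 and Gpr20 higher and Dennd3 and Slc45a4 (-0.65) lower. St3gal1 is the next tested gene and Dennd3, Slc45a4 and Gpr20 lie 12 to 14 tested genes away. Of 12315 windows of this size 66 held as many called genes, none of them on another chromosome, and the median window held 0. Neighbouring windows overlap, so the 66 share called genes and are not separate instances. The 6 measured members of the list of neighbours fixed beforehand were not called as a set in any comparison (smallest adjusted p = 0.152, sex by oxygen).

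**Figure D4:**
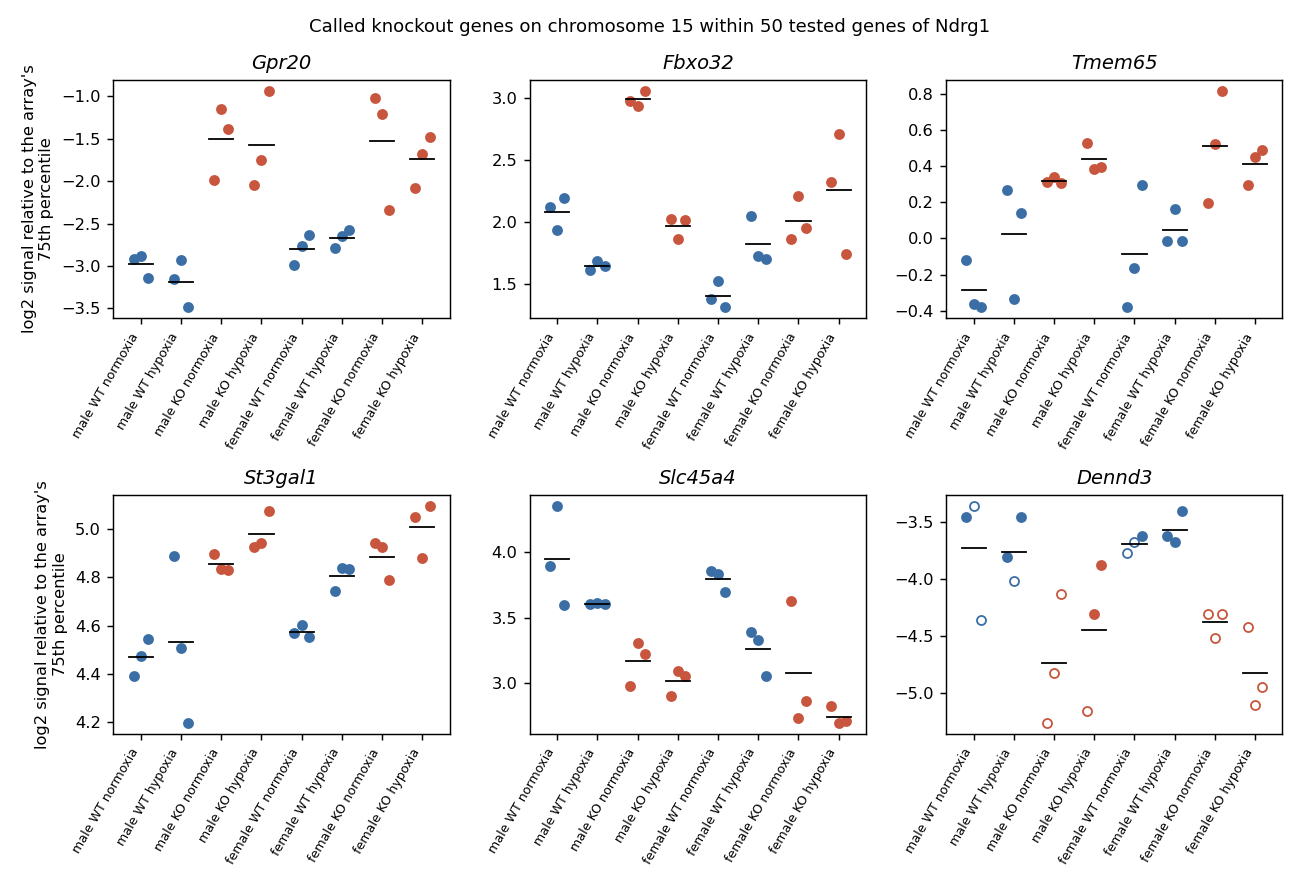
Levels of 6 genes near Ndrg1 on each array (vertical axes, log2 relative to the 75th percentile of the array) for the 8 groups of 3 placentas (horizontal axis), with wild type in blue, knockout in red, filled points well above background, open points not, and bars at group means. The mean log2 difference between knockout and wild type is 1.32 for Gpr20 and -0.65 for Slc45a4.

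In the knockout, lists of stress response genes and of labyrinth markers were called. Of 19 genes of the integrated stress and unfolded protein response 18 were higher, with a median of 0.26; none passed over all genes and 9 rose when adjusted over the list alone (list adjusted p = 3.05e-06). Syncytiotrophoblast markers had a median of -0.17, with 12 of 14 lower, and Syna, which encodes the cell-fusing envelope protein syncytin A, fell by 0.49 on the log2 scale (adjusted p = 0.0481), 6 falling when adjusted over the list alone (list adjusted p = 0.000183). Syna was called in 8 of 14 settings, with values between -0.52 and -0.39 and the highest adjusted p, 0.410, with slide as a fixed block, and leaving out 1 array ended its call for 20 of 24 arrays. With an estimated correlation both gave adjusted p = 0.613. Spongiotrophoblast and glycogen cells were called higher (median 0.21, list adjusted p = 0.00449). Proliferation (median -0.16, list adjusted p = 0.00895), erythroid cells (-0.26, list adjusted p = 0.0189), fetal endothelium (-0.06, list adjusted p = 0.0231), imprinted genes (-0.12, list adjusted p = 0.0272), nutrient transport (-0.17) and oxidative phosphorylation (-0.03; both list adjusted p = 0.0300) were called lower, and these 7 gave adjusted p between 0.685 and 0.775 with an estimated correlation. With slide as a fixed block 12 genes passed, 5 of them among the 56, and with a random block 32, all among the 56. Of the 9 lists 1, the stress response, kept its call with the fixed block. Endothelium (0.011) and erythroid cells (0.0014) turned under it relative to all genes. All 56 genes had the same sign within slide 1 and within slide 3, on arrays that are part of the comparison that called them. Leaving out 1 array gave between 17 genes (without 704) and 431 (without 601), and without the 2 arrays of lowest signal 321 passed.

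In normoxia 15 genes were higher and 66 lower in knockout than in wild type placentas. Gpr20 (1.38 ± 0.22), Fbxo32 (0.76 ± 0.12), Pcgf2 (0.58 ± 0.10), the stress kinase gene Plk3 (0.54 ± 0.11) and Rapgef3, a cAMP-activated exchange factor (0.51 ± 0.10), were higher (6 against 6 arrays). S100a14 (-1.55 ± 0.27), Slc6a13 (-1.40 ± 0.28), Six2 (-1.29 ± 0.22), Pla2g10 (-1.27 ± 0.27), Fndc7 (-1.12 ± 0.16) and Il17re, a receptor subunit of interleukin 17C (-1.05 ± 0.17), were lower. The iron transporter gene Slc11a2 (-0.39 ± 0.07) was the called member of nutrient transport and Tfeb (-0.50 ± 0.09) that of syncytiotrophoblast. Proliferation genes had a median of -0.55, with 21 of 23 lower (list adjusted p = 5.52e-07), oxidative phosphorylation -0.12, with 23 of 25 lower (list adjusted p = 2.61e-06), and interferon response genes 0.34, with 16 of 18 higher (list adjusted p = 4.47e-05). Adjusted over the list alone 2, 8 and 3 members passed. Syncytiotrophoblast (-0.33, list adjusted p = 0.000868), erythroid cells (-0.41, list adjusted p = 0.00113), fetal endothelium (-0.23, list adjusted p = 0.00152), imprinted genes (-0.33, list adjusted p = 0.00486), cholesterol synthesis (-0.19, list adjusted p = 0.00831), nutrient transport (-0.18, list adjusted p = 0.0328) and heat shock proteins (-0.14, list adjusted p = 0.0445) were called lower. The stress response (0.24, list adjusted p = 0.00213), macrophages (0.30, list adjusted p = 0.0153) and p53 and apoptosis (0.12, list adjusted p = 0.0399) were called higher. The 13 lists gave adjusted p between 0.446 and 0.452 with an estimated correlation.

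All 81 genes of the normoxic knockout had the same sign in males within slide 1, on arrays that are part of the comparison that called them. In these 3 against 3 arrays 0 passed (limma, 1011 at unadjusted p under 0.05). With slide as a fixed block 5 of the 13 lists kept call and direction, and erythroid cells turned to 0.12 relative to all genes. With that block 18 genes passed, 2 of them among the 81, with a random block 14, with only the 4 normoxic groups in the fit 0 (2593 at unadjusted p under 0.05) and with the percentile over probes above background on all arrays 13 rises and 23 falls. Leaving out single arrays gave between 1 gene (without 602) and 946 (without 601), and without the 2 arrays of lowest signal 541.

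In hypoxia Ndrg1 itself was the 1 gene called between knockout and wild type (-3.51 ± 0.37, 6 against 6 arrays, adjusted p = 0.000454). Gpr20 was 1.27 ± 0.22 higher and did not pass (adjusted p = 0.195), nor did Dio1, Efna1 or Strip2 (-0.66 ± 0.14, adjusted p = 0.900). Of the 81 genes called in normoxia 73 had the same sign in hypoxia, while over all genes the knockout differences in normoxia and in hypoxia correlated with r = -0.069, and 59 of 100 draws with shuffled residuals gave as high a value. The stress response was again called higher (median 0.32, 16 of 19 higher, list adjusted p = 4.13e-05), as were spongiotrophoblast and glycogen cells (median 0.20, list adjusted p = 0.0152) and oxidative phosphorylation (median 0.06, all 25 higher, list adjusted p = 0.0200), which lay at -0.0080, -0.0018 and -0.00012 relative to all genes, and was not called, with normexp, quantile normalization and the authors' values. Macrophages (median -0.32, list adjusted p = 0.0177) and interferon response genes (median -0.14, list adjusted p = 0.0316) were called lower, and with an estimated correlation these 5 gave adjusted p = 0.999. With slide as a fixed block 7 genes passed, with a random block 1, and 3 of the 5 lists kept their call, while interferon response turned to a median of 0.14 (adjusted p = 0.356). Within slide 3, 0 genes passed in 3 against 3 females (limma, 1520 at unadjusted p under 0.05), and oxidative phosphorylation turned there, with a median of -0.016.

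The differences of hypoxia in wild type and of the knockout in normoxia went together, and both are taken against the same 6 wild type normoxic arrays. Their correlation over genes was 0.734, against a mean of 0.456 in 100 draws of shuffled residuals with the same shared arrays, and 8 draws were as high. The covariance was 0.0854 against 0.0326. With the controls split by sex, so that no array was shared, the correlations were 0.228 and 0.420, with 21 and 6 of 100 draws as high. The genes that fell in both numbered 33, of 584 and 66, against 1.74 for independent lists, and 2 rose in both, of 192 and 15, against 0.13. Independent lists leave out the shared arrays, so part or all of the excess may come from them.

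Between the sexes 30 genes were higher and 72 lower in placentas labelled female. Xist was 16.1-fold higher (SE 0.45 on the log2 scale, 12 against 12 arrays, adjusted p = 0.000218; 10 male arrays above background), and Kdm5c, a demethylase gene that escapes X inactivation, 0.45 ± 0.06 higher. The Y-linked genes Eif2s3y and Ddx3y were at least 32.3-fold and at least 24.6-fold lower in females, where no array measured them, and Uty at least 1.18-fold. Without the library labelled male KO normoxia 201 these bounds were 49.8-fold, 36.5-fold and 1.33-fold. The other 11 males had Xist between -5.84 and -1.89, above background on 9 arrays, against 1.20 in that library. Eif2s3x fell by 0.42 on the log2 scale, but its other kept probe was 0.34 higher, so its direction depends on the probe. The embryonic globins Hbb-y (1.48 ± 0.26), Hbb-bh1 (1.29 ± 0.23) and Hba-x (1.42 ± 0.29), made by the first red cells of the embryo, were higher in females, each in 3 of the 4 strata. For Hbb-y the sex by oxygen difference was -2.89, so its average rests mainly on the normoxic placentas. Sesn2, a stress-induced gene, was lower (-0.50 ± 0.07). The imprinted gene Peg10 was lower (-0.70 ± 0.14) and turned to 0.19 with slide as a fixed block.

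The Y-linked list was called lower in females (list adjusted p = 4.95e-17) and held with an estimated correlation (adjusted p = 0.00217). Erythroid cells (median 0.15, list adjusted p = 0.0117), proliferation (0.14, list adjusted p = 0.0133) and interferon response (0.21, list adjusted p = 0.00117) were called higher and the stress response (-0.08, list adjusted p = 0.0372) lower, with adjusted p between 0.649 and 0.969 with an estimated correlation. All 5 lists kept call and direction with slide as a fixed block. The slides held 8 and 0, 4 and 4, and 0 and 8 male and female arrays, and no slide held both sexes under the same genotype and oxygen. A fixed block for slide called 8 genes, none among the 102, and a random block 3, Eif2s3y, Ddx3y and Uty. With the fixed block the median SE of the 102 went from 0.091 to 0.27. Xist and the Y-linked genes lost their call too, although they mark sex. A call lost under this block therefore does not show that slide made the difference. Leaving out 1 array gave between 48 genes (without 504 or 804) and 266 (without 601), and without the 2 arrays of lowest signal 175 passed.

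Hypoxia differed between the sexes in 240 genes, 217 with a higher and 23 with a lower difference in females. Most of the largest were dim: Olfr1211, an olfactory receptor gene, differed by 4.78 ± 0.78 (adjusted p = 0.0112), a value that rests partly on signals not above background, and it was above background on all 12 arrays of female hypoxic and male normoxic placentas and on 4 of the other 12. Brighter genes with a lower difference in females included Hbb-y (-2.89 ± 0.52), Plcg2, a phospholipase of immune signalling (-1.05 ± 0.24), and Ptprb, an endothelial phosphatase (-1.04 ± 0.24). Prl3a1, a prolactin family gene of the spongiotrophoblast list, had a higher one (1.98 ± 0.40). As lists, proliferation (median -0.83, 22 of 23 lower, list adjusted p = 2.25e-10) and fetal endothelium (-0.55, list adjusted p = 5.07e-06) led the 9 with a lower difference in females, and the stress response (0.39, list adjusted p = 0.00178) was the 1 with a higher difference. These 3 gave adjusted p = 0.488 with an estimated correlation, and 4 of the 10 called lists kept call and direction with slide as a fixed block, under which the stress response turned to -0.14 (adjusted p = 0.382), syncytiotrophoblast to 0.23 and erythroid cells to 0.72. The same 12 arrays of female hypoxic and male normoxic placentas lay on slides 1 and 3, while 8 of the other 12 lay on slide 2. With slide as a fixed block 5 genes passed, none among the 240, and with a random block 0 (limma, 2332 at unadjusted p under 0.05, 3197 without the block). Leaving out single arrays gave between 75 (without 701) and 493 (without 804), and without the 2 arrays of lowest signal 84 passed. Without the library labelled male KO normoxia 201, whose sex genes went against its label, 87 passed. Without it and the 2 arrays of lowest signal 19 did, 15 of them among the 240.

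No gene passed for sex by genotype (limma, 1519 at unadjusted p under 0.05). The smallest p belonged to Olfr901 and Sowaha (both adjusted p = 0.475), Sez6l, Chic1 and Olfr700. As lists, yolk sac endoderm (median 3.24, list adjusted p = 5.74e-09) and cholesterol synthesis (0.30, list adjusted p = 6.39e-07) had a higher knockout difference in females and interferon response a lower one (-0.21, list adjusted p = 0.0476). With an estimated correlation they gave adjusted p between 0.906 and 0.966, and all 3 kept call and direction with slide as a fixed block. The interferon response lost its call for 12 of 24 arrays left out singly. Yolk sac markers varied widely within groups: the mean of the list had an SD of 2.07 there and ran from -1.15 to 5.57 per array. The fixed block called 9 genes and a random block 0 (1334 at unadjusted p under 0.05).

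Of the 31 lists, 9 were called in no comparison. Their smallest adjusted p was 0.0923 for trophoblast giant cells, 0.155 for uterine natural killer cells, 0.211 for epithelium of fetal membranes, 0.0958 for lipid uptake and storage, 0.297 for oxidative stress, 0.189 for immediate early genes, 0.341 for the paralogs Ndrg2, Ndrg3 and Ndrg4, 0.152 for the neighbours of Ndrg1 and 0.0872 for X inactivation and escape. Placental reference genes did not pass for hypoxia or for the knockout on average, among them Igf2 (-0.27 ± 0.10 with hypoxia, adjusted p = 0.130), Pgf (0.80 ± 0.27, adjusted p = 0.104), Flt1 (0.23 ± 0.10, adjusted p = 0.173), Tpbpa (0.29 ± 0.20, adjusted p = 0.431), Prl3b1 (-0.20 ± 0.11, adjusted p = 0.289) and Gcm1 (-0.28 ± 0.32, adjusted p = 0.642). Slc2a3 missed the threshold for hypoxia in wild type (-0.44 ± 0.13, adjusted p = 0.0572). The exception was Syna, which fell in the knockout.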

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

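Tests chosen only after the result was seen were those of the 2 arrays of lowest signal on wild type hypoxia, of the genes around Ndrg1, and of a swap or a mixture for 1 library. Groups of 3 arrays were not tested for single outlying samples. In the weights fitted over all arrays, 601 (0.25), 201 (0.31) and 102 (0.37) had the lowest.

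Hypoxia in wild type called 776 genes. Of 100 splits of the arrays 1, the real one, called as many, with 106 the highest of the others. Splits of single placentas thus seldom gave that count. They cannot exclude placentas that shared a dam or a slide as its source. The 2 arrays of lowest signal (male WT normoxia 102 and female KO normoxia 601) are not the source of most of these calls, since 692 of the 776 were called without both. In that fit 1150 genes passed, and without 601 alone 1518. The rise in number does not clear array 102, since 601 is a knockout and enters this comparison only through the shared estimate of the spread. A slide effect stays open: male fold changes within slide 1 went with female ones across slides at r = 0.145 over genes, above the median of shuffled draws (-0.044) and below their highest (0.745), with 35 of 100 draws as high. With a random slide block 0 genes passed (limma, 3634 at unadjusted p under 0.05), since the median size of the 776 went from 0.41 to 0.37 and their median SE from 0.096 to 0.11, while 545 passed with that block without both arrays, 441 of them among the 776. The slides held 3 and 2, 3 and 1, and 0 and 3 normoxic and hypoxic wild type arrays, which keeps slide open, and a response of the placenta to maternal oxygen stays open too.

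Of the 56 genes called for the knockout, 6 lay within 50 tested genes of Ndrg1, and 66 of 12315 overlapping windows held as many, none on another chromosome. All 6 were called without the 2 arrays of lowest signal as well, which argues against these arrays as their source. DNA of another strain carried along with the targeted allele, or an effect of the deleted locus on its neighbours, may account for them, and these data do not separate the 2 explanations. The labels name 1 strain for all mice. Yet Ifi202b, known to differ between inbred strains, was well above background on 5 knockout and 4 wild type arrays and not on the other 15. The label alone therefore does not settle the strain, and DNA of another strain was not tested for. A response to the loss of the protein itself was not tested either.

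The library labelled male KO normoxia 201 had 0 of 3 measured Y-linked genes well above background, which argues against a mixture with male RNA. A swap with a library labelled female is excluded, since 0 of the 12 had a Y-linked gene well above background. A single wrong sex label, or an exchange with a placenta outside the series, could give these values and stays open. No biological explanation was tested.

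The counts for the other comparisons were set against 100 splits each, the real one included. As many genes were called by 1 split for hypoxia on average (512, highest other 76), 1 for the knockout on average (56, highest other 23), 1 for sex (102, highest other 66), and 1 for sex by oxygen (240, highest other 2). Splits of single placentas thus seldom gave these counts, which does not exclude shared dams or slides as their source. For the knockout in normoxia 4 splits did (81, highest other 820) and for the knockout in hypoxia, where the 1 gene is Ndrg1 itself, 3 did (1, highest other 3). These shares lie under 0.05 by a small margin among 10 such tests, so the counts are unusual among splits of single placentas only at that limit. The 3 splits above the real one for the knockout in normoxia put arrays 102 and 601 in the same arm. Whether splits with high counts do so more often than others was not tested. For hypoxia in knockouts 7 splits called as many (1, highest other 2), so chance cannot be excluded for the count. The 1 gene, Apol11b, was called with each of the 24 arrays left out in turn (adjusted p up to 0.0020). For genotype by oxygen and sex by genotype the count was 0 (limma, 2056 and 1519 genes at unadjusted p under 0.05; highest other 1), which all 100 splits reach whatever the data, so the splits decide nothing there.

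Hypoxia differed between females and males in 240 genes by the interaction test, and slide overlapped with this contrast: 8 of the 12 arrays with a negative sign lay on slide 2 and 0 of the 12 others. With slide as a fixed block 230 of the 240 kept their sign, while their median size went from 1.44 to 0.61 and their median SE from 0.29 to 0.43. That block called 5 genes, none among the 240, and a random block 0. The log2 differences, female minus male, were 4.78 for Olfr1211, 3.07 for Sowaha, 2.82 for Olfr704, 2.77 for Olfr30, 2.70 for Ltb4r2, 2.57 for Olfr901, 2.56 for Olfr94, 2.54 for Crygd, 2.49 for Cd8b1, 2.35 for Nup214, 1.98 for Prl3a1 and 0.66 for Bbc3. They were -2.89 for Hbb-y, -2.85 for Olfr332, -1.42 for Kcnd3, -1.19 for Lefty1, -1.17 for Tmem132c, -1.08 for Ovol1, -1.05 for Plcg2, -1.04 for Ptprb, -0.99 for Galnt16, -0.97 for Emid1, -0.81 for Slc6a6, -0.57 for Slc11a2 and -0.52 for Car9. As list medians, called at the preset correlation and none with an estimated one, the difference was 0.39 for the integrated stress and unfolded protein response, -0.83 for proliferation, -0.26 for syncytiotrophoblast, -0.55 for fetal endothelium, -0.60 for mesenchyme and extracellular matrix, -0.54 for maternal decidua, -0.43 for erythroid cells, -2.22 for yolk sac endoderm, -0.52 for angiogenic factors and -0.30 for imprinted genes. Of these 10, 4 kept call and direction with slide as a fixed block, under which the medians relative to all genes turned to -0.12 for the stress response, 0.25 for syncytiotrophoblast and 0.73 for erythroid cells.

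Lists were also called in the other interactions at the preset correlation, none of them with an estimated one, and with slide as a fixed block 3 of 9 and 3 of 3 kept call and direction. Knockout minus wild type differences of hypoxia had medians of 0.20 for oxidative phosphorylation, 0.70 for proliferation, 0.24 for fetal endothelium, 0.38 for erythroid cells, 0.23 for cholesterol synthesis, 0.22 for imprinted genes, 0.18 for heat shock proteins, -0.63 for macrophages and -0.36 for interferon response. The knockout difference in females minus that in males had medians of 3.24 for yolk sac endoderm, 0.30 for cholesterol synthesis and -0.21 for interferon response.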

How the results depend on the processing

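Tests chosen only after the result was seen were the fits without arrays 102 and 601, also without 201 or with a random slide block, and normexp on the median signal. The random slide block over all arrays was planned. No paired analysis was possible because each array carries its own number and no number is shared between groups. Averaged over oxygen and sex, Ndrg1 was called lower in knockouts under all 14 settings run, between -3.51 and -4.12, and between -3.87 (without 603) and -3.50 (without 601) when 1 array was left out. In normoxia it lay between -4.80 and -3.52, not called with only the groups compared or within slide 1, at adjusted p up to 0.227. In hypoxia it lay between -3.57 and -3.39, not called within slide 3 (adjusted p = 0.361). Counts that moved by over 1.5 times, and the genes and lists that turned, follow by setting. The cause was not tested unless named. Dim probes limit the rest, since 48.1% to 56.9% of spots were well above background.

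Normexp called 229 genes for hypoxia on average, 265 in wild type and 127 for sex by oxygen. Quantile normalization called 173, 135 in wild type, 38 for the knockout in normoxia and 169 for sex. The percentile over probes above background on all arrays gave 6, 155 and 36 for hypoxia on average, hypoxia in wild type and the knockout in normoxia. Without a filter on dim probes the counts were 1 for hypoxia on average, 0 in wild type (limma, 5899 at unadjusted p under 0.05), 24 for the knockout on average, 14 in normoxia and 2 in hypoxia, 41 for sex and 134 for sex by oxygen. That setting moved the median of all genes for sex by oxygen to 0.129. With only probes above background on all arrays, and so fewer genes, they were 0 for hypoxia in knockouts (1127 at unadjusted p under 0.05), 123 for the knockout in normoxia and 106 for sex by oxygen. The mean of a gene's probes gave 58 for sex, trend and robust gave 128 for the knockout in normoxia, and the authors' values gave 49 for hypoxia on average, 79 in wild type, 42 for the knockout in normoxia and 183 for sex. Fits of only the groups compared, with fewer arrays, gave 264 for hypoxia in wild type and 0 for the knockout in normoxia (2593 at unadjusted p under 0.05).

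In the order hypoxia on average, in wild type and in knockouts, knockout on average, in normoxia and in hypoxia, genotype by oxygen, sex, sex by oxygen and sex by genotype, a fixed slide block called 2, 9, 3, 12, 18, 7, 12, 8, 5 and 9 genes and array weights 2606, 2263, 89, 1110, 1183, 25, 27, 470, 459 and 40. A random slide block called 1 for hypoxia on average, 0 in wild type (3634 at unadjusted p under 0.05), 32 for the knockout on average, 14 in normoxia, 3 for sex and 0 for sex by oxygen (2332 at unadjusted p under 0.05). Within slide 1 the knockout in normoxia called 0 (1011 at unadjusted p under 0.05), and within slide 3 the knockout in hypoxia 0 (1520 at unadjusted p under 0.05). Without arrays 102 and 601 the counts were 56 for hypoxia on average, 321 for the knockout on average, 541 in normoxia, 2 in hypoxia, 175 for sex and 84 for sex by oxygen. Also without 201 the first 9 in that order were 95, 1729, 4, 273, 342, 2, 6, 167 and 19. With a random slide block and without 102 and 601 they were 3 for hypoxia on average, 233 and 225 for the knockout on average and in normoxia, 16 for sex and 1 for sex by oxygen.

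With a fixed slide block the difference between the sexes turned to 0.23 for Olfr521, 0.45 for Olfr1143, 0.17 for Arl9 and 0.19 for Peg10, and sex by oxygen to 0.081 for Olfr332. List medians relative to all genes became 0.0079 for syncytiotrophoblast under hypoxia on average. In wild type hypoxia they became 0.056 for it and -0.36 for decidua, and for interferon response in the hypoxic knockout 0.080. For sex by oxygen they became -0.12 for the stress response, 0.25 for syncytiotrophoblast and 0.73 for erythroid cells. Spongiotrophoblast in wild type hypoxia (0.0080) and yolk sac for sex by oxygen (-0.26) kept the sign of the median, while camera's direction turned. The median changed sign, with camera's direction kept and the call ended, for decidua under hypoxia on average (-0.12), inflammation in wild type hypoxia (-0.029), endothelium (0.011) and erythroid cells (0.0014) in the knockout on average, and erythroid cells in the normoxic knockout (0.12) and for genotype by oxygen (-0.17). So did oxidative phosphorylation in the hypoxic knockout with normexp (-0.0080), quantile normalization (-0.0018) and the authors' values (-0.00012), and decidua under hypoxia in knockouts without 102 and 601 or without 601 alone (-0.023 both times). With array weights proliferation between the sexes turned to -0.069. Within slide 3 oxidative phosphorylation in the hypoxic knockout turned to -0.017, and decidua and angiogenic factors under hypoxia in knockouts to -0.27 and -0.18. Within slide 1 proliferation under hypoxia in wild type turned to 0.23. Of 220 values of named genes, the side of the threshold and the direction stayed for 71 with the fixed block, 89 with the random block, 113 without a filter, 155 to 166 under the percentile, quantile and normexp scalings and the authors' values, 192 with the mean of probes, 198 with array weights and 213 with trend and robust. Of 86 called lists 1 was called with an estimated correlation, and other settings called between 71 (quantile) and 99 (array weights) lists, or 73 (without 102) to 90 (without 601) with 1 array left out.

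Leaving out 1 array (in brackets) moved hypoxia on average to 1 (402, 502, 704), 4 (203, 703), 7 (401), 18 (501), 29 (101), 56 (302), 86 (803), 152 (311), 171 (601), 196 (102), 264 (404), 267 (301), 275 (802), 292 (804), 1069 (111) and 1162 (603). Hypoxia in wild type moved to 0 (502, 704, with 4610 and 4504 at unadjusted p under 0.05 by limma), 81 (501), 93 (101), 157 (703), 212 (311), 264 (504), 343 (302), 431 (301), 472 (402), 1277 (111) and 1518 (601). The knockout on average moved to 17 (704), 23 (602), 24 (502), 25 (703), 26 (402), 28 (803), 30 (302, 401), 31 (301, 404), 32 (501), 34 (101, 603), 37 (201), 125 (111) and 431 (601). The knockout in normoxia moved to 1 (602), 12 (603), 13 (502), 15 (101, 202), 24 (201), 25 (501), 31 (504), 38 (401), 42 (203), 44 (402, 704), 47 (302, 703), 52 (701), 123 (111) and 946 (601). Sex moved to 48 (504, 804), 51 (603), 54 (402), 56 (404, 502, 703), 57 (301, 401), 61 (602), 62 (704), 65 (111, 302, 501), 66 (102), 67 (202), 181 (101) and 266 (601). Sex by oxygen moved to 75 (701), 82 (111), 87 (201), 97 (802), 104 (803), 119 (504), 125 (402), 138 (704), 151 (311), 412 (101) and 493 (804). Hypoxia in knockouts (1) moved to 2 (401) and 3 (201, 404), and the knockout in hypoxia (1) to 2 (603) and 3 (404). Genotype by oxygen (0, with 2056 at unadjusted p under 0.05) moved to 1 (311) and 2 (201, 404), and sex by genotype (0, with 1519) to 1 (201) and 2 (311, 404).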

Other observations

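The tests of Ndrg1 against decidua, with and without slide means, were chosen only after the result was seen, as were the genes and lists singled out here.

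Markers of yolk sac endoderm, a membrane that the labels say was taken off, varied widely between placentas of 1 group. The mean of the list ran from -1.15 to 5.57 per array, with a median of 3.01 and an SD within groups of 2.07. Afp, the main serum protein of the embryo, ran from 1.06 to 10.5 and Alb, albumin, from -6.14 to 5.17. Ifi202b, an interferon-inducible gene known to differ between inbred strains, was well above background on 9 arrays, between -1.37 and 0.48. On the other 15 arrays it lay between -6.54 and -4.85.

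As a hypothesis, the Ndrg1 signal left in the knockout placentas may come from maternal decidua, since the dams carried 1 intact allele. Over the 12 knockout arrays Ndrg1 went with the mean of the decidua list, with Pearson r = 0.907 (permutation p = 0.0001, adjusted p = 0.0002) and Spearman rho = 0.867 (permutation p = 0.00045, adjusted p = 0.0009), two-sided, over 100000 permutations. Over the 12 wild type arrays r was 0.253 (permutation p = 0.446) and rho 0.168 (permutation p = 0.602), and these were the 2 relations computed. Without the 2 knockout arrays farthest from the median of the list r was 0.722 (permutation p = 0.0175) and rho 0.770 (permutation p = 0.0122). Markers with a high signal included Prl8a2 (up to 9.51, r = 0.78 with Ndrg1), Cryab (5.67 to 8.17, r = 0.91) and Il11ra1 (5.25 to 6.35, r = 0.93), while Foxo1 went the other way (r = -0.42). With the mean of each of the 3 slides taken off both values r was 0.877 (exact permutation p within slides = 0.000868) and rho 0.798 (exact p = 0.00434). Without the same 2 arrays these were 0.681 (exact p = 0.0361) and 0.696 (exact p = 0.0299), which argues against slide as the whole source of the relation. Other tissue that varies along with decidua was not tested and stays open.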
